A study of Saccharomyces cerevisiae with 180 samples.

How the data were processed

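The study mapped H3 and 4 H3 marks in budding yeast grown in rich medium. Per the labels' protocols, cells were fixed with formaldehyde and chromatin was digested with micrococcal nuclease. A first antibody and a second antibody, or Input, were then used in turn. The authors deposited counts: whole numbers of reads for each nucleosome of an atlas and each library, not normalized. Reads were aligned with Bowtie2 to the sacCer3 build, per the submitters' processing notes, and its version was not given in the sources used here. How reads were assigned to nucleosomes, filtered for duplicates or split by barcode was not given in the sources used here. If duplicate reads were kept, shallow libraries hold fewer independent molecules than reads, and errors from counting are then too small.

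The atlas listed 66360 nucleosomes of 151 bp, and 65032 of them had counts in 180 libraries. Every library was mapped to its strain, first antibody and second step from its title and characteristics, and each formed a group of 1 library. Depth ran from 150 to 2693698 reads (median 110476.5, sum 65297212), and 32 libraries held under 10000. In a 150-read library no single gene can be read. Such libraries still enter sums over zones, yields and correlations across genes. Unless stated otherwise, they also enter the gene means, gene counts, naming of genes and list percentiles taken over antibody combinations.

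Gene names and positions came from a RefSeq gene table of the R64 assembly, the same build as sacCer3, with 1-based coordinates. The table gave no strand, which was read from the W or C of the systematic name. It held 6002 usable protein-coding genes, and 96.4% of their lengths were multiples of 3, so lengths are coding lengths and the start is the start codon. Nucleosomes were placed by their centre: 51629 fell in exactly 1 gene and were used for genes and zones, and 13031 in none and 372 in more than 1 gene were left out of them. Genes of at least 1500 bp (2248) were divided into a 5-prime zone to 500 bp (6646 nucleosomes), a middle zone (6805) and a late zone from 1000 bp (19805).

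Input was read as first-step material without a second antibody, which the labels do not spell out, and all yields depend on this reading. Yield was the total of a library divided by the Input library of the same strain and first antibody, with 0.5 reads added, and was compared across strains of one second step. It measures recovery only if all strains passed that step as 1 pool, which the labels do not state. Co-occurrence was the yield of a second mark from material of a first mark, divided by its yield from H3-first material. Zone values were shares with 95% Wilson intervals and the log2 ratio of late to 5-prime reads. Gene values were log2 of CPM (counts scaled to library size) plus 1, over the first 1000 bp for wild-type levels and over the late zone for changes, in genes with at least 50 reads. The pseudocount understates changes of weakly covered genes and overstates those between a shallow library at 0 and a deep one. A level against 0 reads was bounded with a floor of 3 reads.

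The comparisons, tests and lists were fixed before the data were examined. Recovery in the substitution strains was tested by a one-sided exact permutation test over 64 assignments. Late-zone changes were tested by a two-sided exact permutation test of 6 combinations with a mark against 6 without it, 15 tests with Benjamini-Hochberg adjustment at 0.05. The correlation of both orders over the 6 mark pairs, with the marks in a fixed order, was tested by two-sided exact permutation of pairings. The remaining comparisons had no test. The gene lists were ribosomal protein genes (137 found), ribosome biogenesis (22), glycolysis and fermentation (16), histone genes (10), proteasome (31), respiration and citric acid cycle (16), heat shock and stress (18), galactose genes (8), glucose-repressed carbon metabolism (16), meiosis and sporulation (28), mating and haploid genes (16), genes with cryptic promoters repressed through Set2 and Rpd3S (11), subtelomeric genes within 20 kb of a chromosome end (239) and marker loci (13). In 2 of these lists 1 member was not matched. The median of a list was placed among 10000 random lists of the same size matched on reads.

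The rule for named genes took the marker loci, the 10 largest increases and 5 largest decreases of late-zone K18ac that went the same way in all 6 combinations, the 5 highest wild-type levels per mark, and up to 4 genes per list with the most reads. The text prints a part of them. The plan counted the K36me3 combinations of eaf3 as 1 more than the 8 that exist.

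Other settings fixed in advance changed the normaliser and reference of yields, the zone borders, the gene length, the use of H3 combinations, pseudocounts, read minimums and size factors, and left out shallow libraries or the top 1% of nucleosomes. Settings added after seeing the data left out K79me3 as first antibody, used 5, 4 or 1 of the K18ac combinations, tested means against 0, and used wild-type H3 as reference for set2 and eaf3. The scan for missing loci took genes with at least 100 expected reads and less than 15% of them, and was also added afterwards.

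The scripts were tested on simulated data. A simulated recovery change of -4 over 3 substitution strains came out at -3.99, and a simulated late-zone K4me3 change of 1 in set2 at 1.05. For late-zone K18ac in set2 (2247 genes, 100 raised and 100 lowered), the 6-combination rule recovered 73.0% and 0%. The 5-combination rule recovered 78.0% and 34.0%, and the 4-combination rule 100% and 98.0%. Of the genes with no K18ac change, 4.20%, 4.84% and 8.94% were called raised. These data held the K4me3 shift as well, which also moved those genes, so such shares are not rates without any change. The changed genes had medians of 2.18 and -1.80 over 4 combinations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.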

Results

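Histone marks were mapped in budding yeast by combinatorial indexed immunoprecipitation of mononucleosomes, in which material bound by a first antibody was offered to a second antibody. The values were read counts on nucleosomes of a genome-wide atlas. In 180 libraries, each combination of strain, first antibody and second step was present 1 time, so no value had a replicate and every spread given is a spread over antibody combinations. The first library set held 120 libraries from 4 strains: wild-type H3 and strains with lysine 4, 18 or 36 of H3 replaced by arginine (H3K4R, H3K18R, H3K36R), each with 5 first antibodies (H3, K4me3, K18ac, K36me3, K79me3) and 6 second steps (the same antibodies or Input, read here as first-step material without a second antibody, which the labels do not spell out). The second set held 60 libraries from 3 strains labelled bar1, eaf3 and set2, with the 4 marks as first antibody and the 4 marks or Input as second step. SET2 encodes the H3 lysine 36 methyltransferase and EAF3 encodes a chromodomain protein of the Rpd3S deacetylase complex that binds methylated lysine 36. Depth ran from 150 to 2693698 nucleosome reads per library, with a median of 110476.5 and 32 libraries under 10000. No pair of libraries held identical counts (0 pairs).

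The deleted loci were read first, because they test the strain labels. EAF3 (YPR023C, chromosome XVI, 608826 to 610031) held 92 reads over all libraries of the strain labelled eaf3, 6.10% of the number at the median of the other strains. SET2 (YJL168C, chromosome X, 102227 to 104428) held 57 reads in the strain labelled set2, 2.47% of that number. BAR1 (YIL015W, chromosome IX, 322342 to 324105), a protease that degrades alpha factor, was not depleted in the strain labelled bar1: it held 1030 reads there, 86.8% of the number at the median of the other strains. A scan of 5576 genes, chosen after the counts were seen, found 1 gene under 15% of the expected reads in that strain. It was NAM7 (YMR080C, chromosome XIII, 426712 to 429627), the RNA helicase of nonsense-mediated decay also known as UPF1, with 6 reads where 2759 were expected (0.217%) and reads on 6 of its 17 nucleosomes. The strain labelled bar1 is titled as the wild type of its set and served as the reference for the strains labelled set2 and eaf3, so each direction given for those strains is relative to a strain in which BAR1 was present and NAM7 reads were nearly missing. In the 4 strains of the first set the histone H3 and H4 genes held few reads as well: HHT2 (YNL031C, chromosome XIV, 575640 to 576050) held 15 reads in wild-type H3 and 254 in the strain labelled bar1, and HHF2 (YNL030W, chromosome XIV, 576727 to 577038) held 9 and 290. HHT1 held 32 and 266 reads and HHF1 held 19 and 165 in the same strains. Among the marker loci, LYS2 held 0 reads in wild-type H3 and 3166 in the strain labelled bar1, TRP1 held 12 and 541, and HIS3 held 602 and 299. URA3 and LEU2 held 0 nucleosomes of the table, and no level can be given for them.

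Each substitution removed most of the recovery of the mark on the replaced residue. Second-step yield, the reads of a second antibody relative to the Input library of the same strain and first antibody, was compared with wild-type H3. In H3K4R the K4me3 yield was lower by a log2 change of -5.48 ± 1.16 (SD, n = 4 first antibodies), a 44.8-fold reduction. In H3K18R the K18ac yield changed by -3.71 ± 0.89 (n = 4), 13.1-fold lower, and in H3K36R the K36me3 yield changed by -3.61 ± 1.23 (n = 4), 12.2-fold lower. The other marks moved little: the means of the 9 remaining strain and mark pairs lay between -0.27 (K79me3 in H3K18R) and 0.24 (K4me3 in H3K36R). The mean cognate change was -4.27, the lowest of the 64 possible assignments of cognate marks (one-sided exact permutation test, p = 0.0156, the smallest the design can give). The first antibody gave the same order of size: relative to H3 with Input, K4me3 reads changed by -8.87 in H3K4R, K18ac reads by -4.34 in H3K18R and K36me3 reads by -2.61 in H3K36R. In H3K4R the other 3 marks were also lower relative to H3 with Input, by -1.07 (K18ac), -1.06 (K36me3) and -1.09 (K79me3), on 1 library each. These values and the -8.87 of K4me3 share the H3 library with Input, of 420226 reads in H3K4R and 187203 in wild-type H3. Reads of the 3 marks were not fewer than in wild-type H3: 1113167 against 1039775 (K18ac), 2693698 against 2509006 (K36me3) and 1534724 against 1455269 (K79me3). The shared shift thus need not be a loss of these marks.

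**Figure D1:**
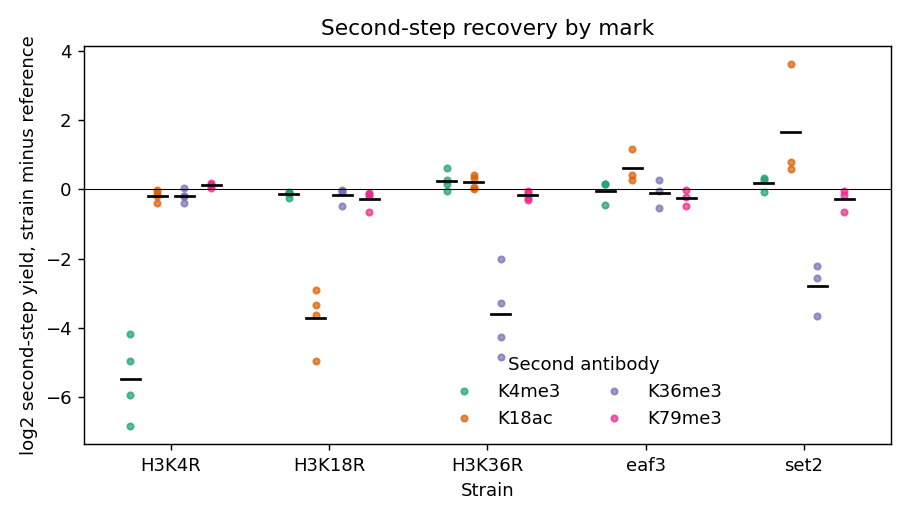
Change in second-step yield (log2, strain minus its reference) for 4 second antibodies in 5 strains, where each point is 1 first antibody and the black bar is the mean. K4me3 in H3K4R (mean -5.48), K18ac in H3K18R (-3.71), and K36me3 in H3K36R (-3.61) and set2 (-2.80) lie far below 0.

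In the strain labelled set2, K36me3 yield was lower than in the strain labelled bar1 by a log2 change of -2.80 ± 0.75 (SD, n = 3 first antibodies), a 6.97-fold reduction with 3 of 3 first antibodies below 0. In the strain labelled eaf3, which keeps the methyltransferase gene, K36me3 yield changed by -0.10 ± 0.40 (n = 3), less than its spread. K18ac yield was higher in both strains for 3 of 3 first antibodies, by 1.66 ± 1.70 in set2 and 0.62 ± 0.48 in eaf3. The set2 value rested on the library of K79me3 followed by K18ac, which held 150 reads in the reference strain and gave 3.62. Without K79me3 as first antibody, a choice made after seeing the data, the K18ac means were 0.69 in set2 and 0.35 in eaf3. K4me3 yield changed by 0.18 ± 0.22 in set2 and -0.04 ± 0.36 in eaf3, and K79me3 yield by -0.28 ± 0.32 and -0.24 ± 0.23. The recovery values of the deletion strains were not tested.

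Sequential precipitation asks how often a pair of marks sits on the same nucleosome. In wild-type H3, K4me3 and K18ac were the pair with the highest joint recovery: relative to H3-first material, K18ac was recovered 2.80-fold more from K4me3 nucleosomes (log2 1.49) and K4me3 2.72-fold more from K18ac nucleosomes (log2 1.44). K79me3 recovery was 3.35-fold lower from K4me3 nucleosomes (log2 -1.74) and 4.51-fold lower from K18ac nucleosomes (log2 -2.17), while the opposite orders gave 0.57 and -0.07. K36me3 recovery from K18ac nucleosomes was 2.93-fold lower (log2 -1.55), and the opposite order gave 0.18. K4me3 with K36me3 gave -0.18 and, with K36me3 first, 1.22. In H3K36R, which lacks K36me3, K36me3-first material gave 390200 reads with K4me3, against 383876 in wild-type H3. The value of 1.22 can thus hold nucleosomes bound off target by the K36me3 antibody, without both marks. K36me3 with K79me3 gave -0.58 and, with K79me3 first, 0.83. With the marks taken in the fixed order K4me3, K18ac, K36me3, K79me3, the values of the 2 orders correlated over the 6 pairs (Pearson r = 0.92, exact permutation p = 0.00556, adjusted 0.0111, and Spearman rho = 0.94, exact permutation p = 0.0167). Which mark of a pair comes first is arbitrary, the coefficients depend on it, and the test did not vary it. The 6 pairs also share marks, Input libraries and H3-first libraries, so they are not independent, although the permutation treats them so. The gap between the 2 orders ran from 0.05 (K4me3 with K18ac) to 2.31 (K4me3 with K79me3), so the correlation does not show that both orders agree. Without the pairs farthest along the first order r was 0.87 over 4 pairs (exact permutation p = 0.167, too few pairs for a low p). The size and sign of single values depended on the reference: with the H3 second step in place of Input, 6 of the 12 values changed sign and all 12 were positive, with co-occurrence K18ac then K79me3 at 1.08. H3 itself was recovered at 48.1 reads per 100 Input reads from H3-first material, but at 3.63 (K4me3 first) to 7.79 (K79me3 first) from material of a mark. A recovery below that of H3-first material thus need not mean that a mark is rarer on those nucleosomes.

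**Figure D2:**
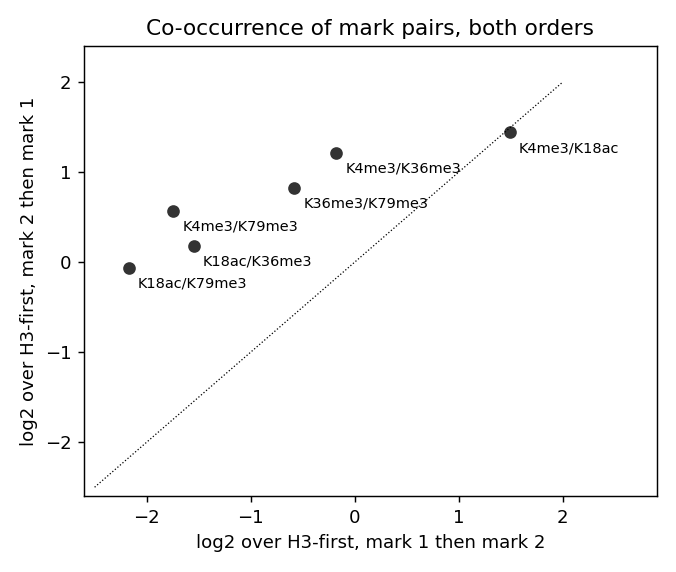
Co-occurrence of 6 mark pairs in wild-type H3 as log2 recovery over H3-first material, with the first-named mark precipitated first on the x axis and second on the y axis, and the dotted line marking equality. K4me3 with K18ac lies on the line (1.49 and 1.44), and the other 5 pairs lie above it.

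Along genes, the marks of wild-type H3 divided into a 5-prime and a gene-body group. Genes of at least 1500 bp of coding length (2248 genes) were divided by distance from the start codon into a 5-prime zone (under 500 bp), a middle zone and a late zone (from 1000 bp). K4me3 placed 49.4% of its zone reads in the 5-prime zone (95% Wilson interval 49.2 to 49.5) and 23.2% in the late zone (23.1 to 23.4). K18ac placed 30.1% (30.0 to 30.3) and 48.6% (48.4 to 48.7). K36me3 placed 9.54% (9.50 to 9.58) and 69.5% (69.5 to 69.6), and K79me3 placed 14.9% (14.8 to 14.9) and 64.3% (64.2 to 64.4). H3 itself, the background, placed 17.7% (17.5 to 17.9) and 62.7% (62.4 to 63.0). The log2 ratio of late to 5-prime reads was 2.87 for K36me3 and -1.09 for K4me3 in wild-type H3, and 2.72 and -0.19 in the strain labelled bar1. Intervals cover counting error only, because PCR reads are not independent molecules.

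**Figure D3:**
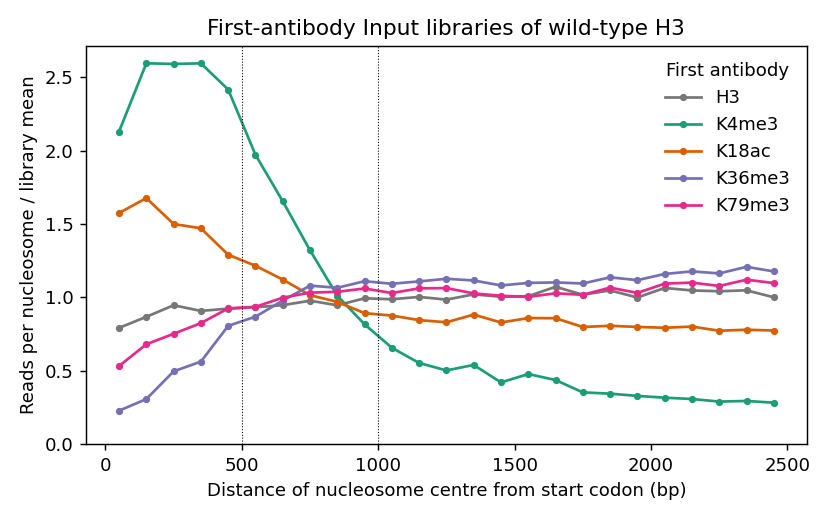
Reads per nucleosome by distance of the nucleosome centre from the start codon (bp), divided by the library mean, for the 5 first antibodies with Input in wild-type H3. K4me3 reached 2.60 at 150 bp and 0.317 at 2050 bp, K18ac 1.68 and 0.794, and K36me3 0.308 and 1.16.

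Over the first 1000 bp of genes in wild-type H3, ribosomal protein genes were placed high for 3 marks, and galactose, glucose-repressed and meiosis genes low for all 4. Each level is the log2 ratio of mark to H3 with Input, and each list is placed among 10000 random lists of the same size and read number. The read number includes reads of the mark itself, so a percentile can part from its median. Histone genes, for example, had a K36me3 median of -1.21 at percentile 46.7, where all genes had -0.06. Ribosomal protein genes had a median K4me3 level of 1.23 (117 genes, percentile 100), K18ac of 1.11 (130 genes, percentile 100) and K36me3 of 0.33 (127 genes, percentile 100), where all genes had medians of 0.88, 0.38 and -0.06. RPS11B, a protein of the small subunit, had a K4me3 level of 1.81 (95% interval 1.09 to 2.54, 230 reads) and RPL4A, of the large subunit, 1.67 (0.97 to 2.37). Genes with paralogs such as these share reads if the counting could split them. Ribosome biogenesis genes had a K4me3 median of 1.43 (22 genes, percentile 91.9) and proteasome genes one of 1.32 (31 genes, percentile 96.1). Galactose genes had a K4me3 median of -1.29 (5 genes, percentile 0.645), with GAL3, a galactose sensor, at -1.79 (-2.54 to -1.04) and GAL2, the permease, at -1.39 (-2.18 to -0.60). Glucose-repressed genes had a K36me3 median of -1.38 (11 genes, percentile 0.01). SUC2, which encodes invertase, had a K36me3 level of -1.19 (-1.82 to -0.55). Meiosis and sporulation genes had a K36me3 median of -1.89 (15 genes, percentile 0.250) and a K18ac median of -0.56 (27 genes, percentile 0.02). IME1, the activator of meiosis, had a K18ac level of -0.70 (-1.31 to -0.08). Subtelomeric genes had a K18ac median of -0.35 (160 genes, percentile 0). Their K4me3 median was -0.02 (90 genes, percentile 0), but this reversed among genes with at least 200 reads (gene lists: percentile of subtelomeric genes, K4me3 in WT H3, 98.8). That minimum counts K4me3 and H3 reads together, from libraries of 758641 and 187203 reads. It thus selects genes high in K4me3 and cannot test the placement.

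Other lists stood apart for some marks. Heat shock and stress genes were low in K79me3 (median -0.51, 15 genes, percentile 0.260) and K18ac (median -0.12, 16 genes, percentile 1.06). Glycolysis and fermentation genes were low in K79me3 (median -1.29, 13 genes, percentile 0.05), with HXK2, the main hexokinase, at -0.95 (-1.53 to -0.37), and unremarkable in K4me3 (0.88, percentile 21.3). The genes with Set2-repressed internal promoters were low in K4me3 (median -0.14, 11 genes, percentile 0) and K18ac (-0.07, percentile 0.735). Respiration genes (K18ac median 0.12, 16 genes, percentile 6.86), mating and haploid genes (0.13, 13 genes, percentile 10.8), histone genes (0.55, 6 genes, percentile 83.4) and marker loci (-0.03, 4 genes, percentile 26.8) were inside the central 95% of random lists for K18ac. In all, 24 list and mark values lay outside the central 95%. The single genes with the highest levels had almost no H3 reads: MSL1, AIM7, DSS4 and LTO1 had 0, and their K4me3 levels were at least 8.39-fold, 5.68-fold, 4.77-fold and 4.19-fold higher than H3 when H3 was set at 3 reads. With H3 summed over the first set (genes with more than 3 H3 reads), the highest K4me3 levels were at MEH1 (6.21-fold) and MRPL23 (5.84-fold). With at least 200 reads required per gene, 4 list values lay outside the central 95%, and K4me3 and K18ac of the ribosomal protein genes were no longer among them. Most of the low values of the galactose, glucose-repressed and meiosis lists were not among them either. This minimum selects genes with many reads of the mark.

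The wild types of the 2 sets were compared as a yardstick. Over 20 shared combinations, the log2 ratio of late to 5-prime reads was higher in the strain labelled bar1 by 0.21 ± 0.43 (SD, n = 20), between -0.46 and 0.99. The 6 combinations with K4me3 were higher by 0.64 ± 0.37 and the 6 with K18ac by 0.41 ± 0.47. The median correlation of a combination across genes was 0.84, where genes are not independent replicates.

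K4me3 lay farther into genes in set2 and eaf3 than in the strain labelled bar1, and the planned test passed in both, but not in H3K36R. With Input, the late share of K4me3 reads was 31.9% in H3K36R and 23.2% in wild-type H3, and 51.6% in set2 (95% Wilson interval 51.4 to 51.7) and 52.6% in eaf3 (52.5 to 52.7) where the strain labelled bar1 had 35.6% (35.4 to 35.8). The late to 5-prime log2 ratio of the 6 combinations with K4me3 was higher by 1.30 ± 0.25 in set2 (6 of 6 higher) and 1.13 ± 0.26 in eaf3 (6 of 6), against 0.49 ± 0.59 and 0.41 ± 0.51 in the 6 combinations without it. The difference passed the two-sided exact permutation test over combinations in set2 (0.81, p = 0.0108, adjusted p = 0.0390) and in eaf3 (0.72, p = 0.0130, adjusted p = 0.0390). In H3K36R the means were 0.71 ± 0.31 (6 of 6 higher) and 0.24 ± 0.53, and the difference of 0.47 did not pass (exact permutation p = 0.0996, adjusted p = 0.149). The H3K36R mean was about as large as the gap of 0.64 ± 0.37 between the wild types of both sets over the same combinations. H3K18R, which keeps lysine 36, also passed for K4me3, with a smaller difference (0.29). The set2 call was lost with a late zone from 1500 bp (late-zone change, K4me3 in set2, 0.83, exact permutation with adjusted p = 0.0519). Both calls for K4me3 were lost when libraries under 10000 reads were left out (0.67 in set2 and 0.60 in eaf3, exact permutation with adjusted p = 0.134) and in genes of at least 2500 bp (0.72 and 0.59, exact permutation with adjusted p = 0.136). Combinations with the same first antibody share material, so p measures the spread over antibody combinations and not over cultures.

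K18ac combinations were higher in the late zone of all 3 strains but did not pass the planned test of a difference from the other combinations. The late share of K18ac with Input was 58.5% in H3K36R (58.4 to 58.7) and 48.6% in wild-type H3, and 63.6% in set2 (63.4 to 63.7) and 63.1% in eaf3 (63.0 to 63.2) where the strain labelled bar1 had 54.1% (54.0 to 54.2). Combinations with K18ac were higher by 1.03 ± 0.43 in set2, 0.87 ± 0.44 in eaf3 and 0.71 ± 0.36 in H3K36R, each in 6 of 6 combinations. Their difference from combinations without K18ac was 0.27 in set2 (exact permutation p = 0.455, adjusted p = 0.524), 0.20 in eaf3 (exact permutation p = 0.548, adjusted p = 0.548) and 0.47 in H3K36R (exact permutation p = 0.0952, adjusted p = 0.149). With combinations of H3 included, both the late-zone change, K18ac in H3K36R (0.56, exact permutation with adjusted p = 0.0247) and the late-zone change, K4me3 in H3K36R (0.45, exact permutation with adjusted p = 0.0451) passed. By construction a K4me3 shift lowers this K18ac difference, because K4me3 is in fewer of the combinations with K18ac than of those without. In simulated data the difference was -0.24, with K4me3 shifted in all long genes and K18ac raised in 100 and lowered in 100. The test thus leans against K18ac, and a missed threshold does not show a lack of change. A looser test against 0, chosen after seeing the data, put all 6 K4me3 and K18ac means of these strains past the threshold (exact sign-flip permutation test, adjusted p = 0.0426 for each). It also passed in H3K4R for K18ac (0.55) and K36me3 (0.48), and in H3K18R for K4me3 (0.39), K36me3 (0.18) and K79me3 (0.21), so it does not set the 3 strains apart.

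K79me3 combinations differed from the reference by less than their spread, by 0.52 ± 0.61 in set2, 0.44 ± 0.53 in eaf3 and 0.10 ± 0.40 in H3K36R (4 of 6 higher in each), below the combinations without K79me3 by -0.76, -0.67 and -0.73. The H3K36R difference passed (exact permutation p = 0.00216, adjusted p = 0.0162), and those of set2 and eaf3 did not (exact permutation with adjusted p = 0.0528 for both). The K79me3 means join 2 directions, because combinations with K4me3 or K18ac were higher in each strain and the others lower. K79me3 with Input and with itself changed by -0.34 and -0.40 in H3K36R, where H3 changed by -0.06 and -0.12. The same combinations changed by -0.12 and -0.25 in set2 and by -0.12 and -0.18 in eaf3. Values of set2 and eaf3 rest in part on K79me3-first reference libraries of 150, 4281, 9216 and 10044 reads (K18ac, K4me3, K79me3 and Input). By the construction of the test a K4me3 shift lowers the K79me3 difference. It was -0.47 in the same simulated data, in which K18ac of some genes was changed too. In H3K4R, combinations with K18ac were higher by 0.55 ± 0.23 against 0.20 ± 0.18 without it (difference 0.36, exact permutation p = 0.0130, adjusted p = 0.0390). In H3K18R, combinations with K4me3 were higher by 0.39 ± 0.06 against 0.10 ± 0.03 (difference 0.29, exact permutation p = 0.00216, adjusted p = 0.0162). Of the 15 tests 5 passed the adjusted threshold of 0.05. The K18ac call in H3K4R was lost without libraries under 10000 reads (late-zone change, K18ac in H3K4R, 0.36, exact permutation with adjusted p = 0.0649). None of its own libraries was that shallow, so its value stayed and the adjusted p alone moved.

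**Figure D4:**
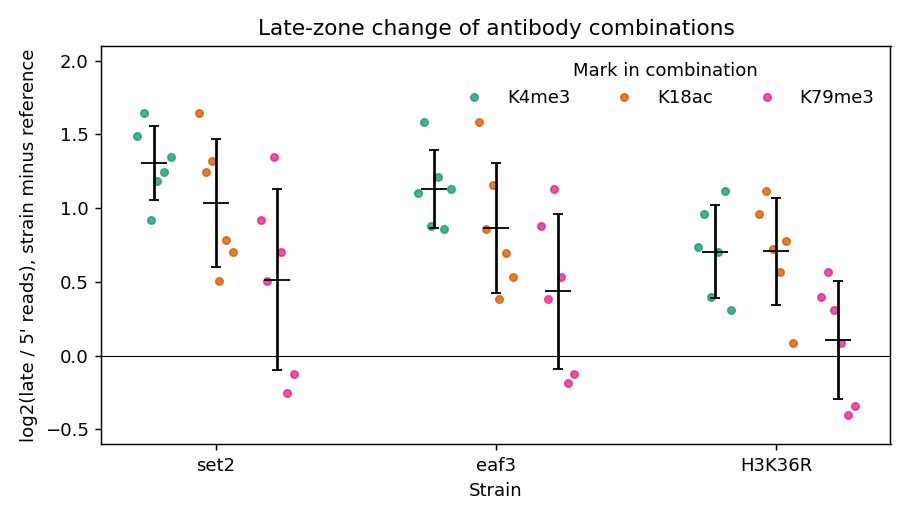
Change in the log2 ratio of late to 5-prime reads (strain minus its reference) for antibody combinations that contain K4me3, K18ac or K79me3, without K36me3 or H3, in 3 strains; each point is 1 of 6 combinations, and bars give the mean and SD. All K4me3 and K18ac points lie above 0, with K4me3 means of 1.30, 1.13 and 0.71.

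K36me3 with Input kept its place along genes in eaf3. Its late share was 69.9% (69.8 to 70.0) there and 70.7% (70.5 to 70.9) in the strain labelled bar1. Over the 8 combinations with K36me3 the late to 5-prime log2 ratio differed between these strains by 0.19 ± 0.47 (between -0.41 and 1.03, higher in 4 of 8). This mean joins 2 directions: combinations with K4me3 or K18ac were higher (0.38 to 1.03), and those with K36me3 alone, K79me3 or Input lower (-0.41 to -0.03). The K36me3-first material left in set2 placed 42.4% in the late zone (41.6 to 43.3) and that of H3K36R 30.6% (30.4 to 30.8).

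At single genes of at least 1500 bp, the only ones measured, late-zone K18ac was higher in set2 than in the strain labelled bar1 in genes of many functions. By the naming rule (higher in all 6 K18ac combinations), the leading genes after NAM7 were CCH1, a calcium channel subunit (YGR217W, chromosome VII, 924696 to 930815), NUM1, a cortical anchor of dynein (YDR150W, chromosome IV, 755628 to 763874), ORC1, a subunit of the origin recognition complex (YML065W, chromosome XIII, 142210 to 144954), MET10, of sulfite reductase (YFR030W, chromosome VI, 213312 to 216419), IML1, FMP27, APC1, of the anaphase-promoting complex, YLR035C-A and VPS13. Their mean log2 changes ran from 3.94 ± 4.11 (CCH1, SD, n = 6 combinations) to 3.62 ± 4.37 (VPS13), spreads as large as the means. The 150-read reference library of K79me3 followed by K18ac and the 15742-read library of K4me3 followed by K18ac set these means. Where such a library held 0 reads of a gene, the change grows with the late-zone reads of the mutant. The ranking thus favours long genes by construction. With K18ac as first antibody, a choice made after seeing the data (4 combinations), the values were 1.31 ± 0.75 for CCH1, 1.28 ± 0.48 for NUM1 and 1.53 ± 0.96 for MET10. They were 1.13 ± 0.47 for IML1, 1.11 ± 0.55 for FMP27 and 1.08 ± 0.65 for APC1. YLR035C-A was at 0.90 ± 0.44, VPS13 at 0.81 ± 0.39 and ORC1 at 1.81 ± 2.04. These 4 combinations, K18ac with Input among them, are part of the 6 that named the genes, so a positive sign was fixed in advance. In the deepest pair of libraries, K18ac with Input, CCH1 was 1.78-fold higher (log2 0.83, 95% interval 0.67 to 0.99) on 691 and 592 reads. NAM7 had the largest value, 7.18 ± 0.65, because the reference strain held almost none of its reads (2 with K18ac and Input).

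Across 2247 genes, 890 were higher in all 6 combinations in set2 and 0 were lower, where independent libraries with no change would give 35.1 each way. That number is too low for this rule, which called 4.20% of genes with no K18ac change raised in simulated data. Those data also held a K4me3 shift, so this share is not a rate without any change. With size factors 265 were higher and 102 lower. These factors were set on the late-zone counts, so they remove a rise shared by most genes and cannot test one. They also left out the 150-read library, which had too few genes, so these counts are not over all 6 combinations. The median gene change was 1.98 over 6 combinations, 1.02 without the 150-read library, 0.61 over the 4 combinations with K18ac first and 0.46 with Input alone. Simulated genes with no K18ac change, but with K4me3 shifted, had medians of 1.31, 0.26 and 0.17 over 6, 5 and 4 combinations. Much of the first value thus arises without a change of K18ac itself. Over those 4 combinations 1280 genes were higher and 68 lower, and with Input alone 84.8% of genes were higher. The 4-combination rule called 8.94% of genes with no K18ac change raised and 0.244% lowered in the same simulated data. In simulated data the 6-combination rule recovered 73.0% of raised genes and 0% of lowered genes, and the 4-combination rule 100% and 98.0%. The absence of lowered genes under the first rule thus carries no weight. The simulated changes, with medians of 2.18 and -1.80 over 4 combinations, were larger than the median seen here.

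**Figure D5:**
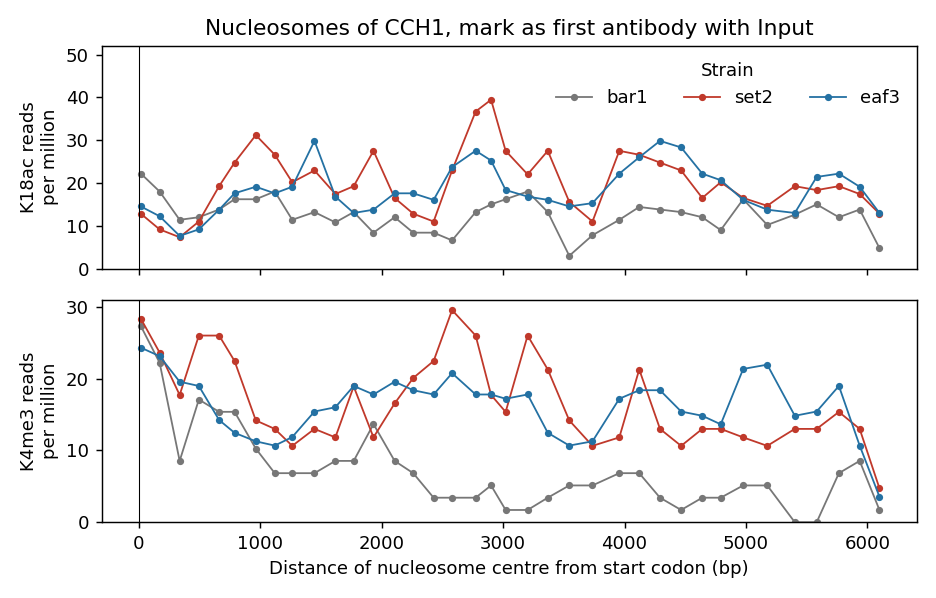
Reads on each nucleosome, scaled to library size (CPM), of CCH1 against distance from its start codon (bp), for K18ac (top) and K4me3 (bottom) as first antibody with Input in the strains labelled bar1, set2 and eaf3. From 1000 bp on, 30 nucleosomes had mean K18ac values of 11.8, 21.1 and 19.6 and mean K4me3 values of 5.07, 15.4 and 15.9 in these strains.

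In eaf3 the genes named by the same rule were ORC1, MET10, CCH1, SIR3, a silencing protein (YLR442C, chromosome XII, 1019315 to 1022251), CYR1, adenylate cyclase (YJL005W, chromosome X, 425157 to 431237), MDL1, VPS13, GCN2, the kinase of the translation factor eIF2 alpha, APC1 and ECM29, a proteasome adaptor. Their 6-combination means lay between 3.60 ± 4.04 (ECM29) and 3.93 ± 3.95 (ORC1). With K18ac as first antibody, SIR3 was at 1.15 ± 0.55, CYR1 at 0.85 ± 0.36 and MET10 at 1.43 ± 0.82. VPS13 was at 0.93 ± 0.28, GCN2 at 1.04 ± 0.73 and ECM29 at 1.04 ± 0.60. As in set2, the naming rule fixed a positive sign of these values, and of those with Input, in advance. With Input alone SIR3 was 1.97-fold higher (log2 0.98, 0.70 to 1.25) and CYR1 1.79-fold higher (log2 0.84, 0.67 to 1.01). Of 2247 genes 269 were higher in all 6 combinations and 0 lower (gene lists: late-zone K18ac genes raised in all combinations, eaf3, were 307 with size factors, and 92 were lowered), 835 and 29 without the library of K79me3 followed by K18ac, and 1081 and 92 over the 4 combinations. The median change was 1.17, 1.06 and 0.47, and 0.39 with Input alone. As in set2, size factors remove a rise shared by most genes and leave out the library of K79me3 followed by K18ac. Because set2 and eaf3 were compared with the same reference libraries, the genes they share are not counted here.

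In H3K36R, compared with its own wild type, the named genes were MDV1, of mitochondrial fission (YJL112W, chromosome X, 205305 to 207449), YPF1, MTC4, RAD30, DNA polymerase eta, EXO84, of the exocyst, TGL1, ROG1, LRE1, UBP7 and DBP7. Their 6-combination means lay between 2.98 ± 2.68 (DBP7) and 3.54 ± 2.60 (MDV1). With Input alone, where the naming rule fixed a positive sign in advance, MDV1 was 2.03-fold higher (log2 1.02, 0.63 to 1.42). MTC4 was 2.38-fold higher (log2 1.25, 0.85 to 1.65) and ROG1 1.97-fold (log2 0.98, 0.60 to 1.35). The rule also named 5 lower genes: YFL040W at -1.63 ± 2.18, the drug transporter QDR2 at -1.60 ± 1.68, GIP1, a meiotic phosphatase subunit, at -1.56 ± 2.25, the allantoin permease DAL4 at -1.55 ± 2.24 and GAL10 at -1.54 ± 1.79. Of 2243 genes 368 were higher in all 6 combinations and 11 lower, and 1013 and 47 over the 4 combinations. With size factors, which remove a rise shared by most genes, 103 were higher in all 6 and 29 lower. The median change was 0.60 over 6, 0.54 over 4 and 0.48 with Input alone, where 87.1% of genes were higher.

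Glucose-repressed genes had a low late-zone K18ac change in set2 and eaf3, outside the central 95% of random lists. By the planned mean of 6 combinations their median was 0.74 in set2 (12 genes, percentile 0 of random lists, all genes 1.98), 0.29 in eaf3 (percentile 1.05, all genes 1.17, and 3.51 and so inside at a pseudocount of 0.5; gene lists: percentile of glucose-repressed carbon metabolism, K18ac in eaf3) and 0.10 in H3K36R (percentile 2.65, inside the central 95%, all genes 0.60). With K18ac first the medians were -0.48 in set2 (6 of 12 lower in all 4 combinations and 1 higher), -0.44 in eaf3 (7 lower and 1 higher) and 0.09 in H3K36R (0 lower and 1 higher), at percentiles 0, 0 and 0.410, so the list lay outside the central 95% in H3K36R as well under this choice. ACS1, acetyl-CoA synthetase, was at -1.18 with Input in set2 (95% interval -1.51 to -0.84) and -0.80 in eaf3 (-1.08 to -0.51), and CYB2, lactate dehydrogenase, at -0.80 (-1.13 to -0.48) and -0.66 (-0.95 to -0.37). CAT8, an activator of gluconeogenic genes, was at 0.35 (0.12 to 0.58) in set2 and 0.37 (0.16 to 0.59) in eaf3. Subtelomeric genes were low as well, with 6-combination medians of 1.47 in set2 (68 genes, percentile 0.01), 0.52 in eaf3 (percentile 0) and 0.25 in H3K36R (67 genes, percentile 0.630). With K18ac first their medians were -0.02, -0.19 and 0.29 (percentiles 0, 0 and 0.03). In set2 15 of these genes were higher and 16 lower in all 4 combinations, in eaf3 7 and 21, and in H3K36R 16 and 9. Many subtelomeric genes, such as the YRF1 helicases, have near-identical copies and their values are uncertain.

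The genes with Set2-repressed internal promoters had 6-combination medians of 2.02 in set2 (10 genes, percentile 38.5), 1.66 in eaf3 (percentile 91.2) and 1.48 in H3K36R (percentile 99.5). In H3K36R 5 of the 10 were higher in all 6 combinations. Among them PCA1, a cadmium transporter, was 2.04-fold higher with Input (log2 1.03, 0.72 to 1.34) and AVO1, of the TORC2 complex, 1.81-fold (log2 0.85, 0.59 to 1.11). K18ac with Input is part of the 6 combinations, so a positive sign was fixed for genes higher in all of them. With K18ac first the medians were 0.83, 0.77 and 0.93 (percentiles 90.0, 97.7 and 98.2), with 7 of 10 higher in all 4 combinations in each strain, and with Input alone no strain had this list outside the central 95%. Meiosis genes were at percentiles 0.750 in set2, 41.0 in eaf3 and 40.1 in H3K36R by the planned mean, and at 0.02, 0.450 and 15.9 with K18ac first, which puts eaf3 outside the central 95% too. By the planned mean galactose genes were at 6.23, 6.14 and 2.91. Of the 14 lists, 3 lay outside the central 95% in set2, 2 in eaf3 and 2 in H3K36R. Heat shock genes (percentile 94.7 in H3K36R), ribosome biogenesis (81.6), proteasome (78.0), respiration (25.2), glycolysis (25.1) and mating genes (70.4) lay inside it in all 3 strains by the planned mean, although with K18ac first glycolysis in eaf3 lay outside (median -0.22, percentile 1.38), and only 2 ribosomal protein and 0 histone genes were long enough to be measured.

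The 2 orders of precipitation were also compared across genes. In wild-type H3 the median correlation of first-then-second with second-then-first libraries was 0.80 over 6 pairs (0.64 for K18ac with K79me3 to 0.94 for K36me3 with K79me3), and 0.65 between libraries that shared no mark. In the strain labelled bar1 the medians were 0.46 and 0.37, with 150 reads in the smallest library. With at least 50 reads required per gene in both libraries, wild-type H3 gave 0.66 for the reciprocal pairs (2 pairs) and -0.070 with no shared mark (1 pair), and the strain labelled bar1 gave 0.65 (1 pair) and 0.48 (2 pairs), 1 of which was as high as 0.64. Genes are not independent replicates.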

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

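All tests in this part were chosen only after the result was seen. The comparisons of the report left out libraries in which the same antibody was used in both steps on a strain that lacks its mark, and these gave more reads per Input read than H3-first material. In H3K4R, K4me3 followed by K4me3 gave 24.1 reads per 100 Input reads, against 0.211 from H3-first material and 74.4 in wild-type H3. In H3K18R, K18ac followed by K18ac gave 5.27, against 0.295 and 94.9, and in H3K36R, K36me3 followed by K36me3 gave 4.31, against 0.558 and 30.9. These yields were not specific to the second antibody: the same H3K4R material gave 17.8 to 23.9 with the other second steps, the H3K18R material 3.23 to 7.75, and the H3K36R material 5.63 to 89.8, all above its self-pair. The H3K4R value rests on 878 reads over 3639 Input reads, and the other 2 on 1979 and 18731 reads.

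The pattern was weighed against 3 technical explanations. Reads assigned to the wrong strain were argued against as the whole cause in H3K4R and H3K36R, where the late to 5-prime log2 ratio of the self-pair lay at least 1.95 from that of any other strain of the first set, but not in H3K18R, where it lay 0.117 from the nearest and among the others. First antibody carried into the second step stays open, since the self-pair differed from the highest other second step by 0.017 (log2) in H3K4R, -0.56 in H3K18R and -4.38 in H3K36R: the excess it predicts was missing in the last 2, but other second steps had their own targets. Nucleosomes bound off target in both steps stay open in H3K36R as well: the self-pair lay -0.35 (log2 late over 5-prime) from the material with Input, farther from H3, but its yield was the lowest of all second steps. No biological explanation was tested.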

How the results depend on the processing

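No paired analysis was possible because every group held 1 library without a replicate number, and the sign-flip tests match libraries by antibody combination only. Alternatives that used fewer K18ac combinations, tested means against 0, left out K79me3 as first antibody or took wild-type H3 as reference for set2 and eaf3 were chosen only after the data were seen; the others were planned. Recovery in the substitution strains kept its direction under all of its alternatives. In libraries of few reads, such as the one of 150, no single gene can be read. The cause of the changes listed here was not tested, except that fewer libraries or genes make a test weaker by construction. Without a normaliser the K4me3 recovery of set2 was 0.65. With the H3 second step as reference, 6 values reversed: co-occurrence K4me3 then K36me3 (3.55), co-occurrence K4me3 then K79me3 (1.98), co-occurrence K18ac then K36me3 (1.70), co-occurrence K18ac then K79me3 (1.08), co-occurrence K79me3 then K18ac (2.56) and co-occurrence K36me3 then K79me3 (2.52). For position profiles in wild type: K36me3 minus K4me3 in WT H3 was 3.64 with a late zone from 750 bp and 4.27 from 1500 bp, and in bar1 2.73 and 3.13.

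In the late-zone tests (exact permutation, adjusted p), the late-zone change, K79me3 in set2, passed from 750 bp (-0.76, exact permutation p = 0.0487), and the late-zone change, K4me3 in set2, failed from 1500 bp (0.83, exact permutation p = 0.0519). In genes of at least 2500 bp K4me3 failed in set2 (0.72) and eaf3 (0.59), with 3 tests past the threshold. With H3 combinations the late-zone change, K4me3 in H3K36R (0.45, exact permutation p = 0.0451) and the late-zone change, K18ac in H3K36R (0.56, exact permutation p = 0.0247) passed, and so did K79me3 in set2 and eaf3 (-0.76 and -0.67, exact permutation p = 0.0451), whose values stay and whose adjusted p alone moves, making 9 tests in all. Without libraries under 10000 reads, K18ac in H3K4R (0.36) failed by its adjusted p alone. K4me3 also failed there in set2 (0.67) and eaf3 (0.60), with 2 tests past the threshold. Testing against 0 put 11 past it. The other 85 late-zone values stayed on their side. With 50 reads required, agreement of the orders in wild-type H3 was 0.66 (2 pairs), and between libraries with no shared mark -0.070 (1 pair, reversed).

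The number of lists outside the central 95% was 4 in wild-type H3 at 200 reads, and subtelomeric K4me3 reversed (gene lists: percentile of subtelomeric genes, K4me3 in WT H3, 98.8). That minimum counts reads of the mark itself, so it selects genes high in the mark. The number of lists was 1 in eaf3 at a pseudocount of 0.5, 4 in H3K36R with 5 combinations, 5 in eaf3 with 4, and 4 in both with Input alone. The median late-zone K18ac change was 2.23 in set2 and 1.33 in eaf3 at a pseudocount of 0.5, and 1.41, 0.80 and 0.50 in set2, eaf3 and H3K36R at 5. With size factors it was 0.55, 0.69 and 0.23, with 265 genes higher and 102 lower in set2, 92 lower in eaf3, and 103 higher and 29 lower in H3K36R. Size factors were set on the same late-zone counts, so they remove a rise shared by most genes and cannot test one. In set2 and eaf3 they also left out the library of K79me3 followed by K18ac, which had too few genes. With 5 combinations 19 genes were lower in set2 (median 1.02), 835 higher and 29 lower in eaf3 (1.06), and 698 and 22 in H3K36R. With 4 combinations 68 were lower in set2 (0.61), 1081 higher and 92 lower in eaf3 (0.47), and 1013 and 47 in H3K36R. With Input alone 1905 were higher and 342 lower in set2 (0.46), 1852 and 395 in eaf3 (0.39), and 1954 and 289 in H3K36R (0.48).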

Other observations

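All tests in this part were chosen only after the result was seen. Across genes of at least 1500 bp, those with more K36me3 in the reference had a larger late-zone K18ac value in the strains labelled set2 and eaf3. With Input, the median log2 change over quartiles of late K36me3 per nucleosome, from lowest to highest, was 0.18, 0.46, 0.57 and 0.64 in set2 (2019 genes) and 0.11, 0.39, 0.48 and 0.55 in eaf3 (2195 genes). In H3K36R (1696 genes) it was 0.26, 0.55, 0.57 and 0.54. K4me3 followed the same order in set2 (0.57, 0.74, 0.78 and 0.78) and eaf3 (0.46, 0.73, 0.79 and 0.86), but in H3K36R it was 0.51, 0.74, 0.56 and 0.44. Across genes the K18ac and K4me3 changes correlated with r = 0.36 in set2, 0.45 in eaf3 and 0.36 in H3K36R, and K18ac change with log gene length at 0.28, 0.34 and 0.19, where genes are not independent replicates. Between the strains, the late-zone change of K4me3 was larger in set2 than in H3K36R by 0.60 ± 0.30 (6 of 6 combinations), and that of K18ac was larger in set2 than in eaf3 by 0.17 ± 0.12 (6 of 6). Both reached the smallest p that 6 combinations can give (two-sided exact sign-flip permutation, p = 0.0312). After adjustment over 9 tests p was 0.0938 (exact permutation), so the tests could hardly pass and leave open whether the strains differ.

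Besides the histone genes, CAN1, the arginine permease (YEL063C, chromosome V, 31694 to 33466), was nearly missing from the strains of the first set: it held 7 reads in wild-type H3 and 1527 in the strain labelled bar1. LYS2 (chromosome II, 469748 to 473926) held 0, 1, 0 and 1 reads in wild-type H3, H3K36R, H3K18R and H3K4R.

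K4me3 lay farther into genes in set2, eaf3 and H3K36R, though the value in H3K36R (0.71) was about as large as the gap between the wild types of both sets (0.64), and 3 technical explanations were weighed. A reference strain of the second set that stands apart stays open for set2 and eaf3: the mean K4me3 change of set2 against wild-type H3 was 1.94, but strain and set are confounded there. Unspecific background would fade on a second pull-down with the same antibody, and the self-pair kept 1.07 of the change seen with Input. This leaves background open, because the late share fell at that step in the reference and in the mutants alike. It fell from 35.6% to 25.0% in the strain labelled bar1, from 51.6% to 43.9% in set2 and from 52.6% to 39.3% in eaf3. A change between strains can then be kept although background fades. Changed digestion or occupancy was argued against in H3K36R, where H3 itself changed by -0.087. It stays open in set2 and eaf3, which had no H3 libraries and where K79me3 with Input, a mark and not bulk chromatin, changed by -0.12. The reference library of that value held 10044 reads. An effect of K36 methylation and its reader stays open as well, and H3K18R, which keeps lysine 36, also had a K4me3 change (0.39).

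K36me3-first material of H3K36R and set2, which lack the mark, lay nearer the 5-prime end than in other strains. Reads from wrong barcodes would keep a late profile, yet the larger late to 5-prime log2 ratio of these strains was 0.35, where the lowest among strains with the mark was 2.68. Unspecific background would follow bulk nucleosomes, yet in H3K36R the ratio lay -2.22 from that of H3, while in set2, without H3 libraries, background stays open and the ratio lay -1.41 from that of K79me3. The K36me3 antibody could bind K4me3 nucleosomes when its own target is gone: in H3K36R the K4me3 yield from this material was 3.51 (log2) above that from H3-first material, against 1.22 in wild-type H3. Other 5-prime targets of the antibody stay open, and no biological explanation was tested.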
